A study of Rattus norvegicus with 41 samples.

How the data were processed

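Small RNA libraries had been made with TruSeq small RNA kits from TRIzol-extracted RNA, per the labels, from fetal cortex and placenta of Long-Evans rats on gestational day 21. Dams of the stressed generations had been exposed to restraint for 20 min and to forced swimming for 5 min on gestational days 12 to 18. The deposited files give a raw whole-number count per mature miRNA and list only miRNAs with at least 1 count, so a miRNA missing from a file was taken as 0 in that library. The submitters' processing notes name the rat build rn6 and the tools CASAVA, Trim Galore, cutadapt, Bowtie, GenomeStudio, methylKit and DESeq without versions or roles, for the miRNA, mRNA and methylation data together. The miRNA annotation, the strand rule and the handling of reads that match several loci are not given in the sources used here.

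The 41 libraries were grouped by tissue and lineage into 14 groups, of 3 libraries each except 2 for cortex of S in F1. Library numbers are unique, so no paired analysis was possible, and the labels do not tie placenta and cortex libraries to the 24 animals named in the series text. No batch label is given, and neither are litters, so p-values measure the spread between these libraries. Cortex library 34 and an F2 control group are not in the deposited set and were not analysed here. The files hold 574 miRNA names, and 572 matched a RefSeq symbol of the GRCr8 annotation, which was used for names and overlapping precursors alone. Chromosomal positions on rn6 are not given in the sources used here. Of 44 pairs of overlapping precursors, 12 have exactly 1 member in the files. MiR-3553 overlaps miR-183, miR-3588 overlaps miR-125b-2, miR-3596a overlaps let-7a-2 and miR-3586 overlaps miR-151, and of these 4 partners only minor or opposite arms are in the files. Counts of these 4 miRNAs therefore cannot be told from counts of the missing arms. MiR-3581 overlaps miR-409, of which both arms are in the files. The main arms of let-7a, let-7g, miR-125b-5p, miR-183, miR-210 and miR-378 are absent from the files and were not analysed here.

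Counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, miRNAs were filtered by filterByExpr with the group and a minimum count of 10, and a quasi-likelihood model (glmQLFit without robust estimation, glmQLFTest) was fitted with 1 coefficient per group. Separate fits were made for placenta (291 miRNAs, 99.9% of counts, biological coefficient of variation 0.211) and cortex (258 miRNAs, 0.187). A fit of all 41 libraries in 14 groups gave the differences of effects between tissues (347 miRNAs, 0.211), and a fit with lineage and tissue terms gave cortex against placenta (291 miRNAs, 0.215). The residual degrees of freedom were 14 in placenta and 13 in cortex, with 7.26 and 6.65 added by the prior. P-values were two-sided and adjusted within a comparison by Benjamini-Hochberg, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F.

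The 20 comparisons, the tests, the miRNA lists and the naming rule were fixed before the data were examined. They were 5 lineage comparisons and 1 comparison of unstressed lineages per tissue, the difference of the stress effect between F3 and F1 per tissue, cortex against placenta, and 5 differences of effects between tissues. In the lineage and control comparisons the text names, among miRNAs with an adjusted p under 0.05, the 10 largest rises and the 10 largest falls. If fewer than 5 passed, the smallest unadjusted p up to 5 miRNAs were added as values that did not pass. For cortex against placenta 12 rises and 12 falls are named, and for differences of effects up to 5 miRNAs. Also named are the 5 most abundant miRNAs per tissue, up to 4 abundant members of a list, and a fixed panel of miR-9, miR-124, let-7b, miR-322 and miR-451, whose further member miR-210 was absent.

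The 16 lists were brain-enriched, stress and glucocorticoid-linked, let-7, miR-17-92 and paralogs, the Dlk1-Dio3 cluster, Sfmbt2 intron families, the miR-322 and miR-503 cluster, epithelial (miR-200 and miR-183 families), erythroid, leukocyte, endothelial, mesenchymal and smooth muscle, striated muscle, liver, oligodendrocyte lineage and hypoxia. Names of 7 older forms were matched by hand. Lists with at least 3 tested members were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The hypoxia list had no tested member, since the main arm of miR-210 is not in the files, and was not analysed here. A floor of 3 counts over a group bounded folds against a count of 0, and 95% counting intervals were given for ratios against 1 to 3 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

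The pipeline was tested on simulated data with 40 changed miRNAs in each of 5 simulations. At a 2-fold change it recovered 69% in placenta F1, 71% in placenta SNN against NNN, 52% in cortex F1, 61% in cortex SNN against NNN and 96% between tissues. At a 4-fold change it recovered 94%, 94%, 88%, 90% and 97%. False calls in those simulations came to 7.91% of all calls in placenta F1, 5.71% in placenta SNN against NNN, 5.41% in cortex F1, 5.62% in cortex SNN against NNN and 3.50% between tissues. Without a change it made 0 calls in 1 simulation of each.

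Alternatives fixed beforehand were median-ratio size factors, no filter, only the groups compared, DESeq2 1.42.0, removal of the 5 most abundant miRNAs, only miRNAs listed in every library, leaving out each library in turn, and the estimated correlation. After the data were seen, robust dispersions and fits without cortex library 33, cortex library 22 or placenta library 26 were added, and list tests that passed were repeated without each library in turn. Other splits of the libraries were all 10 for 3 against 3 or 100 draws, and correlations across libraries used 100000 permutations. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.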

Results

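MicroRNAs, short RNAs that repress target messenger RNAs, were counted by small RNA sequencing in the placenta and the cortex of Long-Evans rat fetuses collected on gestational day 21. Pregnant dams had been stressed by restraint and forced swimming or left unstressed, and the letters of a lineage give 1 dam per generation, S for stressed and N for unstressed. The F1 fetuses were N or S, the F2 fetuses SN or SS, and the F3 fetuses NNN, SNN (stress of the F0 dam alone) or SSS (stress in every generation of dams). Placenta had 21 libraries, 3 in each of 7 groups, and cortex 20 libraries, 3 per group except 2 for S in F1. Total counts per library ran from 174292 to 759255 in placenta (median 371874) and from 83045 to 580409 in cortex (median 343960), with cortex library 33 (N) and library 11 (SS, 89480.0 counts) the shallowest. Libraries of 1 group differed beyond counting noise, with a chi-square of 4.07 to 105 per degree of freedom over 40 within-group pairs. All SN, SS, SNN and SSS libraries carry numbers from 1 to 24, and all N, S and NNN libraries carry numbers from 25 to 42, so each F3 comparison with NNN splits the libraries by number as well as by lineage.

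Placental counts were led by miR-127 of the imprinted Dlk1-Dio3 cluster (14.6% of counts ± 1.92, SD, n = 21), miR-182 (11.8% ± 1.53), miR-143 (9.14% ± 1.29), miR-22 (8.66% ± 0.987) and miR-26a (5.49% ± 0.580). Cortical counts were led by miR-181a (28.3% ± 2.99, SD, n = 20) and the neural miR-9 (16.9% ± 1.36), followed by miR-127 (5.10% ± 0.972), miR-3588 (4.55% ± 0.942) and miR-26a (3.58% ± 0.677). The precursors of miR-3588, miR-3553 and miR-3596a overlap those of miR-125b, miR-183 and let-7a, whose main arms are not in the files, and their counts cannot be told from counts of those miRNAs because the strand rule is not given in the sources used here. Changes are given as log2 fold changes ± SE from edgeR quasi-likelihood tests with Benjamini-Hochberg adjusted p. Levels are normalised CPM (counts scaled to a common library size by TMM), mean ± SD with n = 3 libraries per group unless another n is given. Members called only with the p adjusted over the list alone, and those called only under another setting, are outside the naming rule and were named after their values were seen. An asterisk marks the arm of a hairpin named as the minor one in the older nomenclature.

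The largest rises from placenta to cortex included the neural miR-9. Cortex (n = 20) exceeded placenta (n = 21) by 11.52 ± 0.18 in miR-9 (edgeR adjusted p = 2.58e-42), by 10.43 ± 0.18 in its partner arm miR-9*, by 9.33 ± 0.21 in miR-384-5p, by 9.33 ± 0.19 in miR-325-3p and by 9.22 ± 0.22 in miR-384-3p. Further rises were 8.68 ± 0.19 in miR-488, 8.60 ± 0.19 in miR-708*, 8.17 ± 0.13 in miR-181c*, 7.75 ± 0.21 in miR-504 and 7.72 ± 0.15 in miR-125b-3p. Placenta had no count of miR-137, which was at least 1024-fold higher in cortex against a floor of 3 counts over the group, and the ratio for miR-325-5p was 1316 (95% counting interval 235 to 52039). Cortex had no count of miR-741-3p, miR-881 and miR-196b, which were at least 1437-fold, 922-fold and 649-fold higher in placenta against the same floor. The change from placenta to cortex was -10.11 in miR-743b, -10.02 in miR-293, -9.83 in miR-292-5p and -9.29 in miR-291b. With 1 to 3 counts in cortex, the placental excess was given as a ratio: 3134 for miR-743b* (562 to 123797), 2504 for miR-291a-5p (449 to 98916), 2397 for miR-871 (663 to 19794), 2043 for miR-743a (366 to 80700) and 1459 for miR-466c (404 to 12053). Of the fixed panel, miR-124 (5.27 ± 0.14) and let-7b (3.35 ± 0.10) rose, and miR-322 (-4.64 ± 0.09) and miR-451 (-1.93 ± 0.15), an erythroid miRNA, fell. In the edgeR test 271 of 291 miRNAs differed, 122 higher and 149 lower in cortex.

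All 17 tested brain-enriched miRNAs rose in cortex (median 6.46), and as a set they exceeded the other miRNAs (camera adjusted p = 1.6e-07; adjusted p = 0.00783 with an estimated correlation). In the let-7 family 9 of 10 members rose (camera adjusted p = 0.0112), among them let-7c (4.34 ± 0.09), let-7i (1.32 ± 0.06) and let-7f (0.33 ± 0.08). The growth-linked miR-17-92 clusters had 12 rises and 1 fall among 13 members (camera adjusted p = 0.00572), with miR-93 at 1.90 ± 0.11 and miR-92a at -0.35 ± 0.08. The Dlk1-Dio3 cluster had 42 falls and 1 rise among 48 members (camera adjusted p = 5.08e-05), with miR-541 at -2.77 ± 0.08 and miR-127 at -1.14 ± 0.06. All 8 members of the X-linked miR-322 and miR-503 cluster (camera adjusted p = 0.00402) and all 9 epithelial miRNAs (camera adjusted p = 0.0116) fell, including miR-450a (-5.10 ± 0.08), miR-182 (-7.61 ± 0.25) and miR-141 (-6.41 ± 0.33). For these last 5 lists the call was lost with an adjusted p = 0.260 with an estimated correlation. No call as a set was made for the stress and glucocorticoid-linked list (14 rises and 6 falls of 21, camera adjusted p = 0.0537), the mesenchymal list (5 falls of 5, 0.109), the erythroid list (3 falls of 3, 0.302), the leukocyte list (2 rises and 3 falls of 6, 0.732) or the endothelial list (2 rises and 1 fall of 3, 0.732). Lists too short for a set test had both members of the Sfmbt2 intron families lower in cortex (median -8.84 as fitted and -8.51 with the miRNA absent from cortex at its bound), 1 of 2 liver miRNAs lower and the oligodendrocyte-linked miR-338 higher (3.97 ± 0.16). Counts adjusted over the list alone were equal to these in every list.

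**Figure D1:**
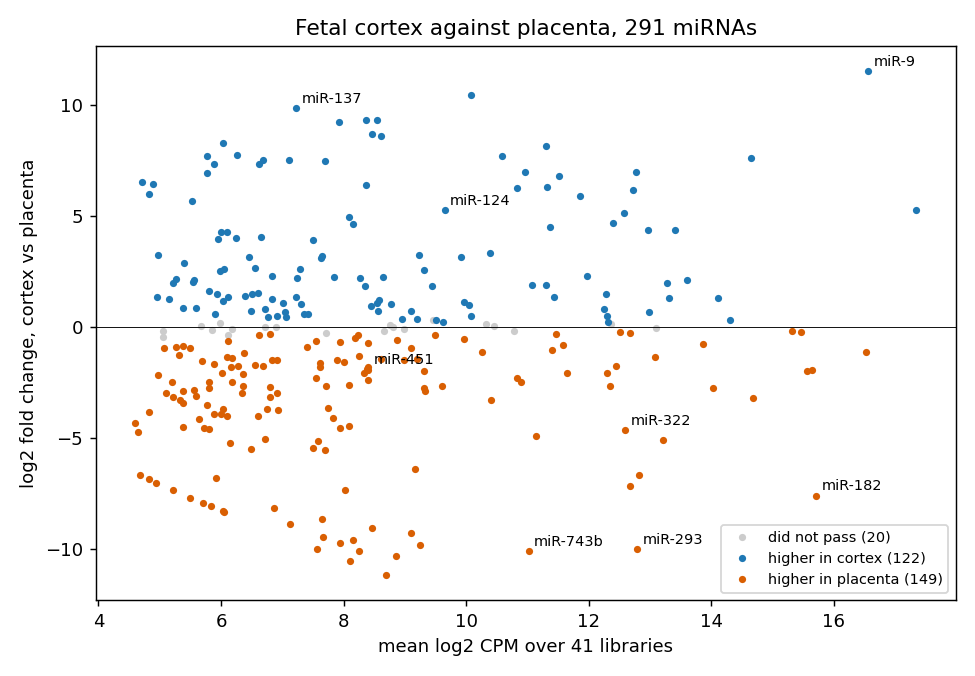
Each point is 1 of 291 miRNAs, with mean log2 CPM over 41 libraries on the x axis and the log2 fold change of cortex against placenta on the y axis. In the edgeR test 122 miRNAs were higher in cortex, 149 were higher in placenta and 20 did not pass, and the extremes are miR-9 for cortex and miR-741-3p for placenta.

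No placental miRNA passed the test for stress of the F0 dam in the F1 generation. The smallest p belonged to miR-411 of the Dlk1-Dio3 cluster, at 6733 ± 110 CPM in S and 10656 ± 1944 in N (-0.66 ± 0.17, edgeR adjusted p = 0.258). The next were miR-31 (-0.90 ± 0.27), miR-300-3p (-0.76 ± 0.23) and miR-15b* (1.18 ± 0.36), each with an adjusted p of 0.266, and miR-666* (-1.01 ± 0.33, adjusted p = 0.306). As a set the 54 tested Dlk1-Dio3 miRNAs were lower in S than the other miRNAs (median -0.27, but -0.10 with total-count scaling, 16 of 54 above 0, camera adjusted p = 0.00133, but adjusted p = 0.856 with an estimated correlation). The median was -0.10 without library 26 and -0.17 without 27, and without 28 it was -0.09 and the call was lost (adjusted p = 0.985). Adjusted over the list alone, 1 Dlk1-Dio3 miRNA (miR-411) and 1 liver miRNA (miR-192) fell. Panel values were 0.41 ± 0.26 for let-7b, -0.21 ± 0.33 for miR-9, 0.10 ± 0.18 for miR-322, -0.18 ± 0.37 for miR-124 and 0.01 ± 0.32 for miR-451. EdgeR called 0 of 291 miRNAs, with 27 at an unadjusted p under 0.05, DESeq2 called 0, and 8.93% of miRNAs had groups that did not overlap where chance gives 10%. Without library 25 the edgeR count was 3, miR-411 and miR-31 (both adjusted p = 0.0408) and miR-192. Without library 26 miR-411 was at -0.43, miR-300-3p at -0.43 and miR-666* at -0.39.

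The F2 comparison asked whether a second stressed generation (SS) added to stress of the F0 dam alone (SN), and no placental miRNA passed. The smallest adjusted p of 0.0796 (edgeR) was shared by miR-19a (126 ± 8.63 CPM in SS and 228 ± 43.5 in SN, -0.86 ± 0.21) and miR-19b (626 ± 29.6 and 1093 ± 299, -0.81 ± 0.20), members of the oncogenic miR-17-92 cluster. The next were miR-493* (-1.10 ± 0.37), miR-20a (-0.95 ± 0.33) and miR-296 (1.59 ± 0.58), each with an adjusted p of 0.646. Adjusted over the list alone, 3 of 11 miR-17-92 miRNAs (miR-19a, miR-19b and miR-20a) fell, against 0 over all miRNAs tested. The 9 brain-enriched miRNAs were higher in SS as a set (median 0.34, 8 above 0, miR-9 at 0.72 ± 0.30, camera adjusted p = 0.0110, but adjusted p = 0.107 with an estimated correlation). The Dlk1-Dio3 list was lower (median -0.14) and the miR-322 and miR-503 list higher (median 0.20), each with a camera adjusted p of 0.0491, but adjusted p = 0.724 with an estimated correlation. Both calls were lost without library 1, 3, 5 or 6 (adjusted p up to 0.390 and 0.418, with a Dlk1-Dio3 median of -0.04 without 1 and a miR-322 and miR-503 median of 0.13 without 3). The brain-enriched call was lost without 5 (0.165; median 0.53 without 3). MiR-20a was at -0.24 without library 1, and miR-493* at -1.70 without 4 and -0.65 without 6. The rest of the panel lay between -0.31 ± 0.33 (miR-451) and 0.50 ± 0.41 (miR-124), with let-7b at 0.29 ± 0.28 and miR-322 at -0.08 ± 0.18. EdgeR called 0 of 291 miRNAs, with 20 at an unadjusted p under 0.05, DESeq2 called 1 (miR-19b), and 15.5% of miRNAs had groups that did not overlap (10% by chance). An F2 control group was not analysed here, since the deposited libraries hold none.

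Stress of the F0 dam alone was set against the unstressed lineage in F3 placenta, and miR-409-5p and miR-99b stood out. For both, every placental library numbered up to 24 lay below every library numbered from 25, the stressed S of F1 being among the latter. Lineage and library set therefore cannot be told apart for them. The same holds for every other call here, since all SNN libraries are numbered up to 24 and all NNN libraries from 25. From NNN to SNN, miR-409-5p fell by 3.48 ± 0.41, from 430.4 ± 215 to 38.3 ± 10.3 CPM (edgeR adjusted p = 7.71e-06), while the other arm of the same hairpin, miR-409-3p, was at 0.02 ± 0.29 (adjusted p = 0.983). MiR-99b fell by 1.31 ± 0.16, from 19939.8 ± 3246 to 8062 ± 221 CPM (adjusted p = 8.13e-06), and its family member miR-100 fell by 1.04 ± 0.21, from 372 ± 32.9 to 182 ± 29.2 CPM (adjusted p = 0.00279). MiR-331 rose by 2.28 ± 0.43, from 9.88 ± 4.32 to 51.3 ± 6.72 CPM (adjusted p = 0.00167). Other rises were miR-142-3p of blood cells (1.35 ± 0.39), miR-675* from the imprinted H19 transcript (1.34 ± 0.36), the Dlk1-Dio3 members miR-154 (1.21 ± 0.32), miR-299* (1.15 ± 0.29), miR-370 (1.10 ± 0.30) and miR-369-5p (0.89 ± 0.23), and miR-542-5p of the miR-322 and miR-503 cluster (0.76 ± 0.23). Other falls among the 10 largest were miR-501* (-1.93 ± 0.37), miR-140* (-1.26 ± 0.32), miR-322* (-1.20 ± 0.25), miR-871* (-1.19 ± 0.21), miR-31 (-0.94 ± 0.26), miR-30e* (-0.94 ± 0.16) and miR-3588 (-0.84 ± 0.20). The 6 calls outside the naming rule, listed here after their values were seen, were miR-143, miR-30a*, let-7f, miR-192, miR-151* and let-7i, all lower.

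By group, 4 of 54 Dlk1-Dio3 miRNAs rose and miR-409-5p fell in SNN placenta (4 and 1 adjusted over the list alone). As a set this cluster was higher (median 0.31, 42 of 54 above 0, camera adjusted p = 0.000508, but adjusted p = 0.801 with an estimated correlation). Its median was 0.52 without library 39, and without 38 it was 0.11 and the call was lost (adjusted p = 0.411). Let-7 had 2 falls of 9 (let-7f -0.61 ± 0.17 and let-7i -0.42 ± 0.13; 2 adjusted over the list alone), and the miR-322 and miR-503 cluster 1 rise and 1 fall of 9 (2 and 1 over the list alone, with miR-503 added). Leukocyte miRNAs had 1 rise of 6 (2 over the list alone, with miR-223 added), mesenchymal miRNAs 1 fall of 5 (miR-143, -0.68 ± 0.14), liver miRNAs 1 fall of 2 (miR-192), the stress list 1 fall of 19 (miR-151*), and the endothelial list 1 fall over the list alone (miR-10a-5p). Of the striated muscle list only miR-499 was tested (-0.24 ± 0.44). Panel values ran from -0.13 ± 0.31 for miR-9 to 0.24 ± 0.32 for miR-451, with miR-322 at 0.23 ± 0.18, miR-124 at -0.04 ± 0.38 and let-7b at -0.01 ± 0.26. EdgeR called 24 of 291 miRNAs, 8 higher and 16 lower, and DESeq2 30, and in every call except miR-142-3p the libraries of both groups did not overlap (34.0% of all miRNAs, 10% by chance). The count was 15 without library 14. Leaving out 1 library ended the calls of miR-154 (library 13, 15, 38 or 39, adjusted p up to 0.0928), miR-369-5p (13, 37 or 38, up to 0.0994), miR-542-5p (13, 14, 15, 37 or 39, up to 0.210), miR-31 (13, 14 or 39, up to 0.141), miR-3588 (13 or 37, up to 0.0529), miR-142-3p (14, 37 or 38, up to 0.234, at 0.81 without 14), miR-675* (14, 37 or 38, up to 0.124), miR-140* (14 or 39, up to 0.0845), miR-370 (15 or 38, up to 0.119) and miR-299* (38, 0.0766).

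With every dam generation stressed, F3 placenta showed changes of like size against NNN. MiR-409-5p fell by 3.49 ± 0.41, to 37.6 ± 18.6 CPM (edgeR adjusted p = 8.95e-06), miR-99b fell by 1.11 ± 0.16, to 9237 ± 718 CPM (adjusted p = 9.78e-05), and miR-331 rose by 2.54 ± 0.43, to 61.5 ± 21.1 CPM (adjusted p = 0.000456). Other rises were miR-154 (1.59 ± 0.32, to 90.7 ± 24.0 CPM), miR-675* (1.32 ± 0.37), miR-299* (1.02 ± 0.29), miR-369-5p (0.85 ± 0.23) and the endothelial miR-126 (0.73 ± 0.19, from 673 ± 105 to 1119 ± 233 CPM). Other falls were miR-501* (-1.55 ± 0.37), miR-322* (-1.19 ± 0.25), miR-871* (-1.15 ± 0.21), miR-30e* (-1.04 ± 0.17), miR-100 (-0.81 ± 0.21), miR-151* (-0.65 ± 0.17), miR-30a* (-0.60 ± 0.17), let-7f (-0.57 ± 0.17) and, outside the naming rule and listed after its value was seen, miR-192 (-0.56 ± 0.16). The Dlk1-Dio3 cluster had 3 rises and 1 fall of 54 (3 and 1 adjusted over the list alone) and was higher as a set (median 0.42, camera adjusted p = 0.00435, but adjusted p = 0.967 with an estimated correlation), a call lost without library 18 (adjusted p = 0.0544) or 38 (0.789, median 0.23). Endothelial miRNAs had 1 rise of 3 (2 over the list alone, with miR-126* added), let-7 miRNAs 1 fall of 9 (2, with let-7i added), and epithelial miRNAs 0 falls of 11 (2, miR-182 and miR-375). The miR-322 and miR-503 cluster had 1 fall of 9 (over the list alone also 1 rise, miR-542-5p), and miR-151* and miR-192 were the single falls of the stress and liver lists. Panel values lay between -0.05 ± 0.18 (miR-322) and 0.13 ± 0.38 (miR-124), with miR-9 at 0.05 ± 0.31 and miR-451 at -0.02 ± 0.33.

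EdgeR called 17 of 291 miRNAs in SSS against NNN placenta, 6 higher and 11 lower, without overlap of the libraries in any call (29.9% of all miRNAs, 10% by chance). DESeq2 called 25, with 15 of the 17 edgeR calls among them. With median-ratio size factors in place of TMM the split was 4 higher and 15 lower. The count was 9 without library 16, 17 or 37, 10 without 38 and 11 without 18. Without 1 library the calls ended for miR-675* (library 16, 18, 37, 38 or 39, adjusted p up to 0.245), miR-299* (any 1 of the 6 libraries, up to 0.179), miR-126 (16, 17, 38 or 39, up to 0.132), miR-100 (16, 17, 18 or 37, up to 0.109), miR-151* (16, 17, 18, 37 or 38, up to 0.125), miR-30a* (16, 17, 18, 37 or 38, up to 0.165), let-7f (any 1 of the 6, up to 0.159), miR-369-5p (17, 18, 37 or 38, up to 0.144) and miR-501* (17 or 37, up to 0.156). MiR-409-5p, miR-99b, miR-331, miR-154, miR-322*, miR-871* and miR-30e* passed without any single library.

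**Figure D2:**
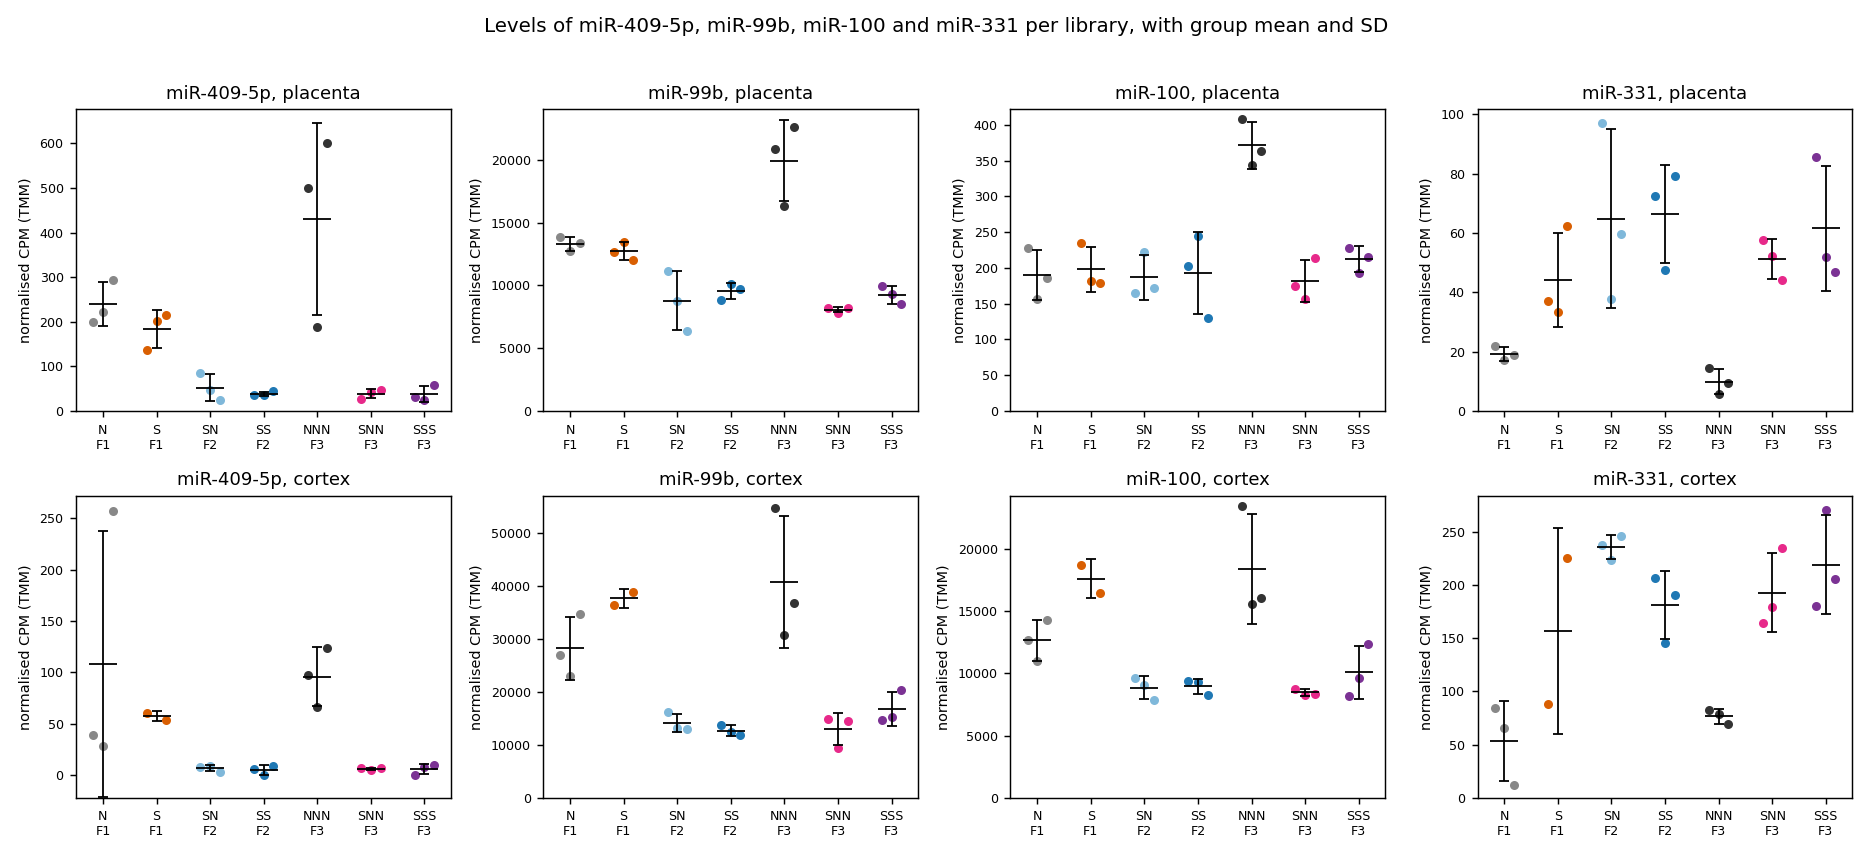
Normalised CPM (y axis) of miR-409-5p, miR-99b, miR-100 and miR-331 in the 7 lineage groups of placenta and of cortex; points are libraries and bars the mean ± SD. MiR-409-5p and miR-99b lie higher in all 3 NNN libraries than in all SNN and SSS libraries of either tissue, and the SN and SS libraries of F2 lie near those of SNN and SSS.

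The contrast of SSS with SNN asked whether repeated stress differed from stress of the F0 dam alone, and no placental miRNA passed. The smallest p belonged to miR-30a (12681 ± 2484 CPM in SSS and 8583 ± 595 in SNN, 0.56 ± 0.15) and the myeloid miR-223 (46.4 ± 1.21 and 215 ± 264 CPM, -2.25 ± 0.61), each with an edgeR adjusted p of 0.204. The next were miR-143 (0.42 ± 0.14, adjusted p = 0.479), miR-503 (-0.92 ± 0.33) and miR-204 (1.47 ± 0.54), the last pair with an adjusted p of 0.602. As sets, the leukocyte list (median -0.52) and the miR-322 and miR-503 list (median -0.11) were lower, each with a camera adjusted p of 0.00325, and the mesenchymal list was higher (median 0.53, camera adjusted p = 0.0115). All 3 were lost with an adjusted p = 0.292 with an estimated correlation. The leukocyte call was lost without library 14 (median 0.01, adjusted p = 0.919; median -0.80 without 13), the miR-322 and miR-503 call without 16 (0.109; median -0.24 without 14 or 17). The mesenchymal call was lost without 14 (0.0584) or 16 (0.109, median 0.29). Without library 14 miR-223 was at -0.53 and miR-503 at -0.19, without 16 miR-143 was at 0.27, and without 17 miR-204 was at 0.37. Adjusted over the list alone, 1 leukocyte miRNA (miR-223) fell and 1 mesenchymal (miR-143) and 1 endothelial miRNA (miR-10a-5p) rose, against 0 over all miRNAs. Panel values ran from -0.28 ± 0.18 for miR-322 to 0.18 ± 0.30 for miR-9. EdgeR called 0 of 291 miRNAs, with 15 at an unadjusted p under 0.05, DESeq2 called 0, and 13.4% of miRNAs had groups that did not overlap (10% by chance). Without library 15 the count was 1 (miR-223, adjusted p = 0.0190), and without library 18 it was 2 (miR-30a and miR-143, both adjusted p = 0.0196).

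Background between generations was read from NNN of F3 against N of F1, since no dam of either lineage was stressed. In placenta miR-501* (1.41 ± 0.37), miR-871* (1.19 ± 0.21, edgeR adjusted p = 0.00406), miR-100 (0.96 ± 0.21), miR-3588 (0.78 ± 0.20), miR-30e* (0.73 ± 0.16), miR-30a* (0.67 ± 0.17), miR-3586-3p (0.61 ± 0.17) and miR-99b (0.58 ± 0.16, adjusted p = 0.0362) rose. MiR-154 (-1.51 ± 0.32), miR-323 (-1.05 ± 0.26), miR-134 (-0.95 ± 0.20), all of the Dlk1-Dio3 cluster, and miR-320 (-0.74 ± 0.20) fell. As a set the Dlk1-Dio3 miRNAs were lower (median -0.34, 6 of 54 above 0, camera adjusted p = 1.68e-09, but adjusted p = 0.743 with an estimated correlation; median -0.12 without library 38 and -0.53 without 39), with 3 falls (4 adjusted over the list alone, with miR-370 added). Over their lists alone miR-322* and miR-143 rose and miR-145 fell. Of the SNN calls against NNN, 8 of 24 returned here in the opposite direction (miR-100, miR-154, miR-30a*, miR-30e*, miR-3588, miR-501*, miR-871* and miR-99b), where 0.990 would be shared in either direction if calls were independent. Of the SSS calls, 7 of 17 did so, all of these except miR-3588, where 0.701 would be shared. NNN enters both sides of this count, so a deviation of its 3 libraries alone would raise it. In 40 simulations without an effect at most 1 call was shared with the control, but these made at most 1 call in a lineage comparison, so they do not measure the share that such a deviation brings. MiR-409-5p stood at 0.85 ± 0.35 (adjusted p = 0.192), and the panel ran from -0.59 ± 0.37 for miR-124 to 0.30 ± 0.32 for miR-9.

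EdgeR called 12 of 291 miRNAs between NNN and N placenta, 8 higher and 4 lower, without overlap of the libraries in any call (21.6% of all miRNAs, 10% by chance). DESeq2 called 17, and a fit of these 6 libraries alone called 0. Without library 26 the count was 13, 4 higher and 9 lower, of which 6 were among the 12. It was 5 without library 27, 3 without library 37 (miR-871* higher, miR-134 and miR-154 lower), and 12 without library 39, 6 higher and 6 lower. A single left-out library ended the calls of miR-3586-3p (any 1 of the 6, adjusted p up to 0.129), miR-99b (any except 38, up to 0.134), miR-320 (25, 27, 37 or 38, up to 0.153), miR-501* (26, 27 or 37, up to 0.264, at 0.94 without 37), miR-100 (26 or 37, up to 0.0812), miR-3588 (26, 27, 37 or 39, up to 0.122), miR-30a* (26, 27, 37 or 38, up to 0.129), miR-323 (27, 37 or 38, up to 0.130) and miR-30e* (37, 0.0812).

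Whether the placental stress effect differed between F3 (SSS against NNN) and F1 (S against N) was tested directly. Of these groups SSS alone has library numbers up to 24, so a difference here cannot be told from a difference between library sets. MiR-409-5p (-3.12 ± 0.55, edgeR adjusted p = 0.00332), miR-99b (-1.05 ± 0.22, adjusted p = 0.0184) and miR-30e* (-1.02 ± 0.24, adjusted p = 0.0266) had lower effects in F3, and miR-411 (0.99 ± 0.24, adjusted p = 0.0367) a higher one. In F1, miR-409-5p stood at 184 ± 42.2 CPM in S and 239 ± 49.1 in N, and in F2 at 38.5 ± 4.37 in SS and 52.2 ± 30.5 in SN. MiR-99b stood at 12735 ± 701 and 13317 ± 570 CPM in F1 (S and N) and at 9552 ± 646 and 8784 ± 2373 in F2 (SS and SN). MiR-331 stood at 44.2 ± 15.8 and 19.3 ± 2.36 CPM in F1 and at 66.4 ± 16.5 and 64.8 ± 30.1 in F2. The Dlk1-Dio3 effect was higher in F3 as a set (median 0.54, 50 of 54 above 0, camera adjusted p = 1.11e-07, but adjusted p = 0.991 with an estimated correlation; median 0.34 without library 27 and 0.32 without 38), with 5 higher (miR-154, miR-369-5p, miR-411, miR-487b and miR-666*) and miR-409-5p lower adjusted over the list alone. Over their lists alone miR-542-5p and miR-126 were higher and miR-322* was lower. EdgeR called 4 of 291 miRNAs, 1 higher and 3 lower, DESeq2 14, and median-ratio size factors in place of TMM gave 3, all lower. The count was 1 without library 18, 28, 29 or 37, 2 without 38 and 8 without 30. Leaving out 1 library ended the calls of miR-411 (any except 25 and 39, adjusted p up to 0.159), miR-99b (18, 28, 29 or 37, up to 0.0756) and miR-30e* (18, 25, 28, 29, 37 or 38, up to 0.0912).

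In F1 cortex, with 2 S libraries against 3 N libraries, no miRNA passed for stress of the F0 dam. The smallest p belonged to the Dlk1-Dio3 member miR-541 (2749 ± 467 CPM in S, n = 2, and 3934 ± 473 in N, -0.52 ± 0.15) and to miR-331 (157 ± 96.8 and 53.8 ± 37.6 CPM, 1.25 ± 0.38), each with an edgeR adjusted p of 0.450. The next were miR-449a (-1.31 ± 0.43), miR-142-3p (2.10 ± 0.74) and miR-375 (-1.48 ± 0.54), each with an adjusted p of 0.484. No list passed the camera test, and none had a call adjusted over the list alone. Panel values were 0.81 ± 0.35 for miR-451, 0.33 ± 0.19 for miR-124, 0.33 ± 0.19 for let-7b, 0.28 ± 0.17 for miR-9 and 0.28 ± 0.20 for miR-322. EdgeR called 0 of 258 miRNAs, with 24 at an unadjusted p under 0.05, DESeq2 called 0, and 21.3% of miRNAs had groups that did not overlap (20% by chance). The count was 1 without library 32 (miR-15b) and 2 without library 35 (miR-331 and miR-449a, both adjusted p = 0.0240), where the lone S library was assumed to vary like the other groups. Library 36 carried much of these values: without it miR-449a was at -0.71, miR-375 at -0.81, miR-331 at 0.43 and miR-142-3p at 0.999. Without library 35 miR-449a was at -2.49 and miR-375 at -3.01.

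Repeated stress in F2 (SS against SN) left no cortical miRNA past the test. The smallest p belonged to miR-10a-5p (78.4 ± 19.6 CPM in SS and 154 ± 70.0 in SN, -1.13 ± 0.39) and the neuronal miR-128 (7029 ± 1719 and 9852 ± 1638 CPM, -0.49 ± 0.17). The next were miR-504 (-0.49 ± 0.19), miR-136 (0.51 ± 0.20) and miR-27a (-0.57 ± 0.24), and the edgeR adjusted p of all 5 was 0.9999. Adjusted over the list alone, 1 endothelial miRNA (miR-10a-5p) fell, and no list passed the camera test. Panel values ran from 0.05 ± 0.30 for miR-451 to 0.24 ± 0.17 for let-7b, with miR-9 at 0.07 ± 0.15, miR-124 at 0.08 ± 0.17 and miR-322 at 0.12 ± 0.18. In edgeR 0 of 258 miRNAs passed, with 7 at an unadjusted p under 0.05, DESeq2 called 0, and 10.1% of miRNAs had groups that did not overlap (10% by chance). MiR-10a-5p was at -0.71 without library 7, and miR-128 at -0.30 without library 10.

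F3 cortex of the SNN lineage differed from NNN in miRNAs that were also called in placenta. MiR-409-5p fell by 3.84 ± 0.69, from 95.6 ± 28.6 to 6.23 ± 0.820 CPM (edgeR adjusted p = 0.00176), miR-99b fell by 1.65 ± 0.21, from 40677 ± 12469 to 12965 ± 3020.0 CPM (adjusted p = 5.2e-05), and miR-100 fell by 1.12 ± 0.17, from 18353 ± 4425 to 8465 ± 263 CPM (adjusted p = 0.000209). MiR-501* (-2.17 ± 0.43), miR-30e* (-0.79 ± 0.17), let-7f (-0.79 ± 0.19) and miR-30a* (-0.74 ± 0.20) also fell. MiR-331 rose by 1.33 ± 0.32, from 76.9 ± 7.05 to 193 ± 37.03 CPM (adjusted p = 0.0208). By list, let-7 had 1 fall of 13 (1 adjusted over the list alone) and Dlk1-Dio3 1 fall of 37 (over the list alone 1 rise and 2 falls, with miR-154 and miR-540 added), while erythroid miRNAs had 2 rises (miR-144 and miR-451) and mesenchymal miRNAs 1 fall (miR-143) over the list alone, against 0 over all miRNAs. No list passed the camera test. Panel values were 0.73 ± 0.28 for miR-451, -0.31 ± 0.15 for miR-9, 0.28 ± 0.17 for miR-322, -0.20 ± 0.17 for miR-124 and -0.14 ± 0.17 for let-7b.

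EdgeR called 8 of 258 miRNAs in SNN against NNN cortex, 1 higher and 7 lower, without overlap of the libraries in any call (24.0% of all miRNAs, 10% by chance), DESeq2 called 13, and a fit without cortex library 33 (N, F1), chosen after the data were seen, called 27. The count was 4 without library 21 and 5 without library 40 or 41. Leaving out 1 library ended the calls of miR-30a* (library 20, 21, 40, 41 or 42, adjusted p up to 0.209), miR-331 (21, 40, 41 or 42, up to 0.134), let-7f (21, 40 or 41, up to 0.134) and miR-30e* (21, 0.0660).

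SSS cortex showed falls of similar size against NNN. MiR-409-5p fell by 3.88 ± 0.73, to 5.88 ± 5.15 CPM (edgeR adjusted p = 0.00267), miR-99b fell by 1.28 ± 0.21, to 16745 ± 3166 CPM (adjusted p = 0.00162), and miR-501* (-1.94 ± 0.44), miR-30e* (-0.91 ± 0.17), miR-100 (-0.86 ± 0.16), miR-30a* (-0.82 ± 0.20) and the brain-enriched miR-488 (-0.68 ± 0.17) fell as well. MiR-331 (1.52 ± 0.32, to 219 ± 46.5 CPM) and miR-30e (0.69 ± 0.16, from 357 ± 46.9 to 576 ± 66.8 CPM) rose, the latter opposite to the other arm of its hairpin. MiR-3553 passed at 2.40 ± 0.63 (adjusted p = 0.0302), but its 266 ± 309 CPM rested on library 22, without which it was at 0.81 (adjusted p = 0.435), and its libraries overlapped those of NNN. Epithelial miRNAs had 0 calls of 5 over all miRNAs and 2 rises adjusted over the list alone (miR-182 and miR-429, median 1.58). In library 22 miR-182 stood at 3333 CPM against 268 to 612 in the other cortex libraries (scaled by total count, not by TMM). Brain-enriched miRNAs had 1 fall of 21 and Dlk1-Dio3 miRNAs 1 fall of 37, with equal counts over the list alone, and no list passed the camera test. Panel values ran from -0.38 ± 0.15 for miR-9 to 0.52 ± 0.29 for miR-451.

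EdgeR called 10 of 258 miRNAs in SSS against NNN cortex, 3 higher and 7 lower, 9 of them without overlap of the libraries (25.97% of all miRNAs, 10% by chance). DESeq2 called 12, 2 higher and 10 lower, and only 6 of the 10 edgeR calls were among them. A fit without cortex library 33, chosen after the data were seen, called 19. The count was 5 without library 40. Leaving out 1 library ended the calls of miR-3553 (library 22, 40, 41 or 42, adjusted p up to 0.435), miR-488 (22, 23 or 40, up to 0.133), miR-30e (23, 24, 40 or 41, up to 0.101), miR-501* (23 or 40, up to 0.0781) and miR-30a* (23, 24, 40 or 41, up to 0.0830).

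Between SSS and SNN cortex no miRNA passed, and the smallest p belonged to miRNAs that were high in library 22. MiR-3553 was at 2.38 ± 0.58 (edgeR adjusted p = 0.151) and miR-182 at 2.05 ± 0.57 (1304 ± 1653 CPM in SSS and 313 ± 21.7 in SNN, adjusted p = 0.222). MiR-429 had 63 counts in SSS, 62 of them in library 22, and 1 in SNN (edgeR adjusted p = 0.538). The ratio of 79.4 (95% counting interval 13.7 to 3186) therefore rests on that library. The next were miR-484 (-0.47 ± 0.16) and miR-92a (-0.40 ± 0.16). The 5 epithelial miRNAs were higher in SSS as a set (median 2.05, camera adjusted p = 0.0151, but adjusted p = 0.207 with an estimated correlation; median 0.16 and adjusted p = 0.536 without library 22, and 0.0727 without 21), with 3 rises adjusted over the list alone (miR-182, miR-200b and miR-429). MiR-182 is also in the stress list, where it was the single rise over the list alone. Panel values ran from -0.25 ± 0.17 for miR-322 to 0.09 ± 0.17 for miR-124. EdgeR called 0 of 258 miRNAs, with 12 at an unadjusted p under 0.05, DESeq2 called 1 (miR-3553), and 14.7% of miRNAs had groups that did not overlap (10% by chance). Without library 23 or 24 the count was 2, miR-3553 and miR-182 (both adjusted p = 0.00562 without 23, and 0.0201 and 0.0215 without 24). Without library 22 they were at 0.80 and 0.16.

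Unstressed cortex of F3 and F1 (NNN against N) gave no call. The smallest p belonged to miR-218a (0.92 ± 0.25), miR-136* (0.55 ± 0.15), miR-323 (1.02 ± 0.28), miR-423 (-1.22 ± 0.36) and miR-3596a (-0.59 ± 0.18), each with an edgeR adjusted p of 0.115. The let-7 family was lower in NNN as a set (median -0.41, 1 of 13 above 0, camera adjusted p = 0.00266, but adjusted p = 0.530 with an estimated correlation), with 3 falls adjusted over the list alone (let-7d, let-7d* and let-7e). Library 33 (N) stands apart from the other cortex libraries on the first principal component (18.2 against -2.96 to 1.94). Without it the let-7 median was -0.22 (camera adjusted p = 0.00903) with 0 falls over the list alone, miR-423 was at -0.35 (adjusted p = 0.720) and miR-3596a at -0.34 (0.441). The let-7 call was lost without library 42 (median -0.25, adjusted p = 0.122), and the median was -0.62 without 40. Also over their lists alone miR-218a, miR-323, miR-136* and miR-126* rose. Panel values ran from -0.19 ± 0.17 for let-7b to 0.54 ± 0.33 for miR-451. The edgeR count was 0 of 258 miRNAs, with 36 at an unadjusted p under 0.05, DESeq2 called 17, and 12.0% of miRNAs had groups that did not overlap (10% by chance). The count was 14 without library 31 (miR-218a adjusted p = 0.0395, miR-423 0.00778, miR-3596a 0.00517) and 13 without library 32 (miR-423 and miR-136* 0.0157, miR-323 0.0176).

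The cortical effect in F3 (SSS against NNN) differed from that in F1 (S against N) in miR-99b (-1.70 ± 0.31) and miR-100 (-1.34 ± 0.24), each with an edgeR adjusted p of 0.00307. As in placenta, SSS alone of these groups has library numbers up to 24, so lineage and library set cannot be told apart here. MiR-99b stood at 37628 ± 1740.4 CPM in S (n = 2) and 28236 ± 5962 in N of F1, and at 12646 ± 1026 in SS and 14096 ± 1736 in SN of F2. MiR-100 stood at 17599 ± 1558 CPM in S (n = 2) and 12649 ± 1675 in N of F1, and in F2 at 8978 ± 606 in SS and 8850.2 ± 919 in SN. MiR-409-5p stood at 57.3 ± 4.78 CPM in S (n = 2) and 108 ± 129 in N of F1, and at 6.74 ± 3.23 in SN and 4.97 ± 4.66 in SS of F2. Its N mean rests on library 33 (257 CPM), with 39.2 and 28.1 CPM in the other N libraries. MiR-331 stood at 157 ± 96.8 CPM in S (n = 2) and 53.8 ± 37.6 in N of F1, and at 236 ± 11.2 in SN and 181.2 ± 31.6 in SS of F2. EdgeR called 2 of 258 miRNAs, both lower, with 31 at an unadjusted p under 0.05, and DESeq2 called 3 (with miR-3553 added). Without library 33 the count was 5, with miR-30a*, miR-409-5p and miR-501* added, and without library 35 it was 0 (miR-99b adjusted p = 0.0546, miR-100 0.0603).

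SNN and SSS shared most of their calls against NNN. In placenta 16 miRNAs were called in both, 5 higher and 11 lower, where 0.165 and 0.605 would be shared if calls were independent, and they included miR-331, miR-154, miR-409-5p, miR-99b and miR-100. In cortex 7 were called in both, miR-331 higher and 6 lower, where 0.0116 and 0.190 would be shared. Both comparisons use the same 3 NNN libraries, which raises the overlap. Simulations without an effect shared 0 calls, but made at most 1 call in placenta and 2 in cortex, so they give no measure of it. Over all miRNAs 81.4% had the same sign in both placental comparisons against 66.8% in 40 simulations without an effect, with a covariance of 0.262 against 0.0567. In cortex the share was 81.4% against 68.0%, with a covariance of 0.251 against 0.0879. These simulations drew each miRNA on its own, although miRNAs vary together in the libraries, and only their means are given. Whether the gap exceeds the spread of such shares was therefore not measured. The 3 controls cannot be divided between the comparisons, so the part of this gap owed to their own deviation was not measured either.

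Across tissues the F3 calls met in the same miRNAs. Among 202 miRNAs tested in both, SNN had 18 calls in placenta and 8 in cortex, and 8 were shared (0.713 if independent): miR-331 higher, and miR-409-5p, miR-99b, miR-100, miR-501*, miR-30a*, miR-30e* and let-7f lower. SSS had 14 and 9 calls, and 7 were shared (0.624 if independent), all of these except let-7f. Both tissues have the same split by library number, and their libraries may come from the same animals. A difference between library sets or litters would therefore also give shared calls, and the overlap is not an independent replication. The effect itself differed between tissues for miR-3553 alone, higher in cortex by 2.59 ± 0.59 in SSS against NNN (edgeR adjusted p = 0.0310) and by 2.37 ± 0.56 in SSS against SNN (adjusted p = 0.0485). Both calls ended without cortex library 22 (at 1.047 and 0.83, adjusted p = 0.9998 each). The first also ended without library 16, 17, 18, 38, 39, 41 or 42 (adjusted p up to 0.312), the second without any 1 of libraries 13 to 21 (up to 0.259), and without library 23 or 24 the counts were 3 and 4, with miR-182 and miR-429 in both and miR-200b in the second.

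The tests of the difference between tissues in F1, in F2 and in SNN against NNN gave 0 calls in edgeR and 0 in DESeq2, with 15, 15 and 11 miRNAs at an unadjusted p under 0.05. The smallest p for SNN against NNN was that of miR-3588 (0.92 ± 0.23, adjusted p = 0.0724), and without library 15 the count was 1 (miR-3588). DESeq2 called miR-3553 in each of the SSS contrasts. As sets, the Dlk1-Dio3 effect was lower in cortex than in placenta for SNN against NNN (median -0.12, camera adjusted p = 0.00278, but adjusted p = 0.844 with an estimated correlation) and for SSS against NNN (median -0.20, 0.0231, but adjusted p = 0.765 with an estimated correlation). The first was lost without library 19, 38 or 42 (adjusted p up to 0.662), with medians from -0.36 (39) to 0.00222 (42). Its median also moved by over 1.5 times without 15, 19, 20, 21, 38, 40 or 41. The second was lost without 16, 18, 22, 38, 41 or 42 (up to 0.936), with medians from -0.39 (39) to -0.06 (38). Its median also moved by over 1.5 times without 18, 23, 40 or 42. In SSS against SNN the effect was higher in cortex for the epithelial list (camera adjusted p = 0.00126, with miR-182, miR-200b and miR-429 called over the list alone in both SSS contrasts) and the leukocyte list (0.0148), both with an adjusted p = 0.176 with an estimated correlation. The epithelial call was lost without library 22 (median 0.84 in all and -0.05 without it, adjusted p = 0.955; 1.37 without 23 and 1.47 without 24). The leukocyte call was lost without 14, 18, 20 or 22 (up to 0.551, median 0.54 in all and 0.01 without 14). Of 232 list tests over all comparisons 23 passed with the preset correlation and 1 with an estimated one, that of brain-enriched miRNAs between tissues.

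**Figure D3:**
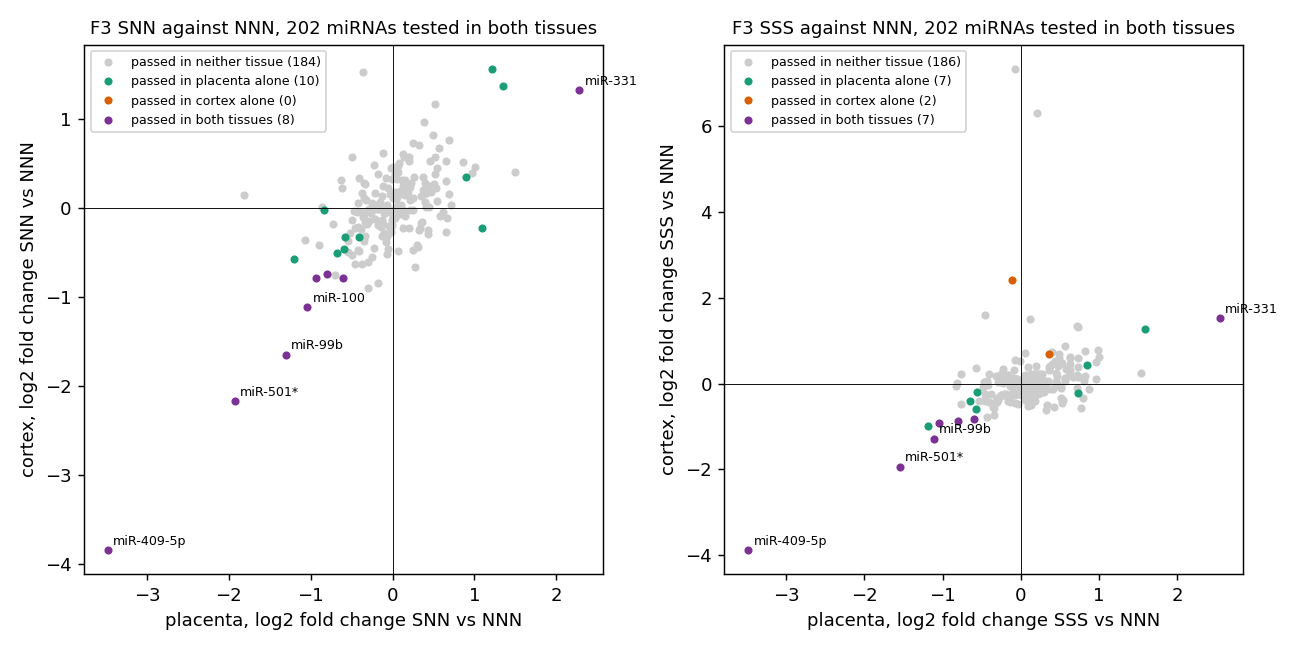
Log2 fold change against NNN in placenta (x axis) and in cortex (y axis) for 202 miRNAs tested in both tissues, with SNN in the left panel and SSS in the right. In SNN 8 miRNAs passed in both tissues and 10 in placenta alone, and in SSS 7 passed in both, 7 in placenta alone and 2 in cortex alone; miR-409-5p lies lowest on both axes.

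Scaling by total count in place of TMM moved the median log2 change of all miRNAs by 0.17 in placenta F1, 0.19 in SNN and 0.10 in SSS against NNN placenta, and -0.21 in the placental control. In cortex it moved it by 0.22 in SNN and 0.23 in SSS against NNN, -0.10 in the control and 0.30 in the generation difference. For cortex against placenta the shift was -0.42 (and -0.19 with median-ratio size factors, from a TMM median of -0.34), and for the tissue differences -0.28 in F1 and 0.10 in SSS against SNN. Median-ratio size factors moved the placental generation difference by -0.18 and the tissue difference in SNN by -0.10. No list called above changed the sign of its median under either scaling, but some medians moved by over 1.5 times. With total-count scaling the Dlk1-Dio3 median went from -0.27 to -0.10 in placenta F1, from 0.31 to 0.51 in SNN against NNN placenta and from -0.34 to -0.56 in the placental control. With median-ratio size factors and with total-count scaling, the miR-322 and miR-503 median in SSS against SNN placenta went from -0.11 to -0.20 and -0.19, and the Dlk1-Dio3 tissue difference in SNN against NNN from -0.12 to -0.21 and -0.19.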

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

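The tests on library numbers, on stress of the F0 dams, on the other arm of each hairpin and on library 22 were chosen after the results were seen, and the splits of the libraries were planned. A direct test found the stress effect in placenta to differ between F3 (SSS against NNN) and F1 (S against N) for miR-409-5p (-3.12 ± 0.55), miR-99b (-1.05 ± 0.22), miR-30e* (-1.02 ± 0.24) and miR-411 (0.99 ± 0.24, log2 ± SE). In both tissues SSS alone of these groups has library numbers up to 24, so this test cannot tell lineage from library set. For this difference 5 of 100 splits, the real one included, gave at least the real 4 calls, so chance cannot be excluded, and the highest other split gave 13. These splits mix NNN, which differed from SSS and from N, with the other groups, and no other structure among the samples was tested. Of these calls, miR-411, miR-99b and miR-30e* each ended when library 18, 28, 29 or 37 was left out (adjusted p up to 0.0912, 0.0756 and 0.0912 in those 4 fits), and miR-409-5p alone was called without library 18. In cortex the same test passed for miR-99b (-1.70 ± 0.31) and miR-100 (-1.34 ± 0.24), both lost without library 35 (adjusted p = 0.0546 and 0.0603), and no splits were counted because S has 2 libraries. Effects differed between tissues for miR-3553, by 2.59 ± 0.59 in SSS against NNN and by 2.37 ± 0.56 in SSS against SNN. For the first, 29 of 100 splits gave at least the real 1 call, with 19 in the highest other, and for the second 5 of 100 did, with 1 in the highest other, so chance cannot be excluded for either. The split with 19 calls kept all lineage labels in cortex and reversed them all in placenta, which turns a lineage difference shared by both tissues into a tissue difference.

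In placenta 25 miRNAs were called in SNN or SSS against NNN, with a median change of 0.94 in size. Stress of the F0 dams acting alike, at like size, in F1 and F3 is argued against for the set by a median S minus N change of 0.0646 in F1 (quartiles -0.05 to 0.35). A smaller shared effect stays open, since 16 of 25 had the F3 direction and the set was picked for its F3 change. MiR-331 (1.18 against 2.41 in F3), miR-31 (0.90 against 0.77), miR-192 (0.45 against 0.57), miR-3588 (0.37 against 0.63) and miR-143 (0.35 against 0.47) went with a shared effect. A change of the whole precursor is argued against for the falls, since over 7 hairpins the other arm moved by -0.0480 in the direction of the called arm (upper quartile 0.17) where the called arm moved by 1.17, but it stays open for the rises, where the other arm was higher in all 6 hairpins, by 0.464 against 0.95. For the whole set, the F2 minus F1 change in the F3 direction was 0.174 (quartiles 0.01 to 0.46) against 0.94 in F3. That is less than a difference between library numbers 1 to 24 and 25 to 42 would give as the sole cause for the whole set, but it cannot exclude one. The 25 miRNAs were picked for their F3 change, which raises its size by an amount not measured. The upper quartile also lay only just under the limit set for it after the results were seen. Generation and stressed lineage, which also differ between F2 and F1, could have offset such a difference. In the F3 direction 19 of 25 miRNAs moved, and 5 passed (miR-409-5p 2.18 against 3.48 in F3, miR-99b 0.51 against 1.21, miR-30e* 0.46 against 0.99, miR-331 1.17 against 2.41 and miR-369-5p 0.64 against 0.87). Over all 291 placental miRNAs 32 passed in either direction. For no single miRNA of the 25 can library number be told apart from a lineage stressed since F0. The F2, SNN and SSS libraries are all numbered up to 24 and all from stressed lineages, and F2 and F1 also differ in generation. MiR-409-5p and miR-99b are also fully separated by library number. Also open, and untested, are an effect of ancestral stress seen from F2 on, and litters or handling particular to the NNN libraries, from which 8 of the 24 SNN calls returned in the opposite direction against unstressed N.

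In cortex 11 miRNAs were called in SNN or SSS against NNN, with a median change of 0.99 in size. Stress of the F0 dams acting alike, at like size, in F1 and F3 is argued against for the set by a median S minus N change of 0.0400 in F1 (quartiles -0.45 to 0.25), with 6 of 11 in the F3 direction. This set too was picked for its F3 change. MiR-331 went with a shared effect, at 1.25 ± 0.38 in F1 (0.43 without library 36) against 1.33 and 1.52 in F3. The N group of F1 also holds library 33, with 12.0 CPM of miR-331 against 61.6 to 277 in the other cortex libraries (scaled by total count). A change of the whole precursor stays open, since only 3 hairpins had their other arm tested, with a median of 0.0642 in the direction of the called arm (from -0.69 to 0.46), and among them the arms of miR-30e moved in opposite directions. The F2 minus F1 change in the F3 direction was 0.743, with all 11 miRNAs in that direction and 9 past the test, and 5 of them (miR-99b, miR-409-5p, miR-501*, miR-30e* and miR-488) are fully separated by library number. Library set and stressed lineage therefore cannot be told apart in cortex, since every F2, SNN and SSS library has a number up to 24 and every other library a higher one, and an inherited effect of stress of the F0 dams that is absent in F1 stays open and untested.

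In cortex library 22 (SSS) 7 of the 13 epithelial miRNAs with a count stood above the other 19 cortex libraries. Among them were miR-182 at 3333 CPM against 268 to 612, miR-429 at 190.1 against 0 to 36.1 and miR-200b at 95.1 against 0 to 35.8. The rest did not, among them miR-375 at 131.8 against 17.8 to 184.7 and miR-203 at 12.3 against 0 to 48.3. MiR-3553, which is not in the epithelial list, stood at 647 against 20.8 to 132. These levels are CPM scaled by total count and not by TMM. Placental RNA in the library is argued against, since the 2.50% of placental RNA that the miR-182 level would need implies 193 counts of 5 placental miRNAs where 4 were found (Poisson upper limit 10.2). Cells of another epithelium are a candidate explanation that these counts do not settle, since 7 of 13 epithelial miRNAs with a count were highest in library 22 where 0.65 would be by chance, and the list was examined because of this library. A biological difference between the fetuses stays open and untested.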

How the results depend on the processing

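The fits with robust dispersions, those without library 33, 22 or 26 and the leave-outs for list tests were chosen after the results were seen. Named values outside the fixed panel and the list members kept their sign under every alternative. The panel and the list members were not part of this check, and some list medians given above did change sign without 1 library. The balance of calls turned in the placental control (8 higher and 4 lower) without library 26 (4 and 9) or 37 (1 and 2) and was even without 39 (6 and 6). It also turned in the cortex generation difference (0 and 2) without a filter (8 and 4), and in cortex against placenta (122 and 149) with only miRNAs listed in every library (94 and 89). Among named miRNAs, 49 of 96 calls passed in every alternative run for them, including miR-409-5p and miR-99b in all 4 F3 comparisons with NNN and miR-331 in placenta. For named values outside the leave-outs, the same side of the threshold was kept by 118 with DESeq2 (7 became calls, 1 was lost), 124 with median-ratio size factors (7 lost), 105 without a filter (13 gained, 13 lost), 76 with only the groups compared (20 lost), 104 with miRNAs listed in every library (3 lost), 126 without the 5 most abundant miRNAs (3 lost) and 128 with robust dispersions (3 lost). The DESeq2 tally does not cover every named value, so its 1 loss understates the difference between the methods. DESeq2 shared 6 of the 10 edgeR calls in SSS against NNN cortex and 15 of the 17 in SSS against NNN placenta. Leaving out 1 library kept 1478, lost 171 and added 17.

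Without a filter the counts were 1 in placenta F1, 2 in placenta F2, 4 in placenta SSS against SNN, 2 in the placental generation difference, 7 in cortex F1, 4 in cortex SSS against SNN, 18 in the cortex control, 12 in the cortex generation difference, 441 in cortex against placenta, and 1, 5 and 4 in the tissue differences of SNN against NNN, SSS against NNN and SSS against SNN. More miRNAs are tested there, and otherwise the cause was not tested. DESeq2 gave 1 in placenta F2, 14 in the placental generation difference, 13 in cortex SNN against NNN, 1 in cortex SSS against SNN and 17 in the cortex control, and the cause was not tested. With only the groups compared the placental control gave 0, with fewer libraries behind the dispersion. Median-ratio size factors and robust dispersions each gave 0 in both SSS tissue differences. Without library 33 the counts were 27 in cortex SNN against NNN, 19 in cortex SSS against NNN and 0 in the tissue difference of SSS against SNN, and without library 26 the tissue difference of SNN against NNN gave 1. The cause was not tested for any of these. With an estimated correlation 1 list test passed in place of 23.

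Leaving out each library in turn gave counts of 0 to 3 in placenta F1, 0 to 0 in F2, 15 to 19 in SNN and 9 to 12 in SSS against NNN, 0 to 2 in SSS against SNN, 3 to 13 in the control and 1 to 8 in the generation difference. In cortex the ranges were 0 to 2, 0 to 0, 4 to 8, 5 to 11, 0 to 2, 0 to 14 and 0 to 5 in the same order. Cortex against placenta gave 268 to 273, and the tissue differences 0 to 0 in F1, 0 to 0 in F2, 0 to 1 in SNN against NNN, 0 to 3 in SSS against NNN and 0 to 4 in SSS against SNN. Where a leave-out left 1 S library in cortex, that library was assumed to vary like the other groups. The planned pseudocounts and value filter for normalised files were not run, because the files hold counts. With totals down to 83045 counts, miRNAs under a mean of a few counts per library were outside the tests.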

Other observations

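Library 33 and miR-204, miR-375, miR-448 and miR-34c were singled out after their values were seen, while the tests on held-out miRNAs, on depth and on splits of the libraries were fixed before their results were. Over the 20 cortex libraries Pearson's r with miR-449a was 0.83 for miR-448 (Spearman's rho 0.75), 0.78 for miR-375 (0.67), 0.71 for miR-34c (0.64) and 0.52 for miR-204 (0.82), where that of miR-204 did not pass (permutation p = 0.0505, adjusted 0.0674) and its rho did (adjusted p = 0.00016). Library 36 (S, F1) was the lowest of the 20 for miR-449a, miR-375, miR-448 and miR-34c. Without the 2 libraries farthest from the median of miR-449a (7 and 36) r was 0.61 for miR-448 (permutation p = 0.00639), 0.41 for miR-375 (p = 0.0883), 0.43 for miR-34c (p = 0.0733) and 0.62 for miR-204 (p = 0.00107). A varying share of ciliated epithelium such as choroid plexus in the dissected cortex is a candidate explanation that these counts do not settle. The held-out arms of miR-34b and miR-764 come from the same loci as miRNAs singled out here. A positive r was therefore likely beforehand and does not by itself point to ciliated epithelium. Summed, these arms varied with miR-449a at r = 0.540 (permutation p = 0.0204, adjusted over 8 relations 0.0407) and rho = 0.453 (permutation p = 0.0466, adjusted 0.0622). Their r was 0.74 within groups, and 0.37 without the same 2 libraries (permutation p = 0.133), so the relation rests on those libraries. Taken apart, the arms of miR-34b had r = 0.465 (permutation p = 0.0484, adjusted 0.0674) and those of miR-764 r = 0.368 (permutation p = 0.108) with rho = 0.194 (permutation p = 0.410), so neither passed after adjustment. Library depth is argued against, with r = 0.0125 (permutation p = 0.951).

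Cortex library 33 (N, F1), the shallowest, had 17.6% miR-181a (95% Wilson interval 17.4 to 17.9) where the other 19 cortex libraries had 25.7% to 32.3%. In CPM scaled by total count and not by TMM, it had 855 of miR-204 against 2940 to 7207 and 5322 of miR-423* against 407 to 807. On the same scale it had 265 of miR-409-5p against 0 to 120.1 and 12.0 of miR-331 against 61.6 to 277.

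Other splits of the libraries were counted for each comparison of groups of at least 3. With 6 libraries 10 splits exist, too few for a share under 0.05. The real counts and the highest of the other splits were 24 and 0 in placenta SNN against NNN, 17 and 0 in placenta SSS against NNN, 12 and 2 in the placental control, 8 and 0 in cortex SNN against NNN and 10 and 0 in cortex SSS against NNN, and in each of these 1 of 10 splits reached the real count. In placenta F1 (0 and 1), placenta F2 (0 and 0), placenta SSS against SNN (0 and 0), cortex F2 (0 and 0), cortex SSS against SNN (0 and 0) and the cortex control (0 and 6) the real count was 0, which all 10 splits reach whatever the libraries hold. The split with 6 calls set cortex libraries 31, 41 and 42 against 32, 33 and 40, and its cause was not tested. For cortex against placenta 1 of 100 splits reached the real 271, with 187 in the highest other. Chance is therefore unlikely, and 1 of 100 is the smallest share that these splits, the real labels included, can give. For the tissue differences in F2 (0 real and 1 in the highest other) and in SNN against NNN (0 and 18) the real count was likewise 0, so 100 of 100 splits reach it and nothing follows about chance. The split with 18 calls kept all lineage labels in cortex and reversed them all in placenta.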
